A study of Mus musculus with 8 samples.

How the data were processed

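Messenger RNA was measured on 8 Illumina MouseRef-8 v2.0 bead arrays, per the labels. Peritoneal macrophages of C57BL/6 mice, WT or lacking the Fcγ chain, were plated overnight in medium with 10% serum and 15% L929-conditioned medium as a source of M-CSF, and cells that did not adhere were discarded. They were then left unstimulated or given IFNγ (10 ng/ml) for 6 h. Total RNA was DNase-treated, amplified and labelled with biotin, per the labels' protocols. GenomeStudio is named in the submitters' processing notes, with its version not given in the sources used here. Group and replicate number were taken from the sample titles, 2 samples in each of 4 groups. No slide or batch is given in the sources used here.

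The values used are the deposited intensity values of the series' value file, with a column per sample, on a linear scale from 82.1 to 22479. The sorted values of the 8 columns differed by at most 0.0048 on the log2 scale, so the authors' intensity values were already normalised between arrays, by a method not given in the sources used here. They were not background-subtracted, as the lowest values show. A second deposited table names its arrays by number only. Its 16 columns of values, 8 of signal and 8 of detection p, could not be assigned to samples, and none of their values enters the results given. The planned correction with detection p (neqc) and the planned filter on detection p could therefore not be run as planned. A first version with a filter that counted detection p over those 8 columns was set aside after its results had been seen, because the columns have no samples. The fallback fixed beforehand was used: normexp background correction with an offset of 50 on the deposited intensities, with no detection filter. Its quantile step was left out, because the values were already normalised between arrays. The offset keeps dim probes from large chance folds and understates the fold changes of dim genes.

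The value file holds 25697 probes. The platform annotation gave a single gene symbol for 23978, none for 1719 and several for 0. Of the named probes, 23962 matched the reference gene table (GRCm38.p6) by gene identifier, which changed 0 symbols. That table served only for names, the chromosome and the order of genes. A gene was represented by the probe with the highest mean over all arrays, which left 16593 genes, 4777 of them with more than 1 probe. Other probes of the named genes had the same sign in 56 of 62 cases for the IFNγ response in WT and 65 of 70 in FcgKO, in 45 of 48 and 52 of 58 for FcgKO against WT without and with IFNγ, and in 14 of 17 for the difference of responses. Fewer were called. Where the probe used was called, the other was called with the same sign in 36 of 51, 39 of 50, 9 of 18, 18 of 31 and 2 of 9 cases, in the order given. For Pparg, another probe rose in WT where the probe used fell, and both were called.

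Log2 values of all 8 arrays were fitted with 1 mean per group (limma 3.58.1, lmFit and eBayes, R 4.3.3 with version 1.17.8 of data.table), with 4 residual degrees of freedom, a prior of 6.56 degrees of freedom and a prior SD of 0.0805. Contrasts were the IFNγ response in each genotype, FcgKO against WT in each condition, and the difference of the responses. P-values were adjusted by Benjamini-Hochberg over all genes, and a gene was called at an adjusted p below 0.05. Arrays have no read depth. The lower end of the scale was taken as each array's median probe, under which 5855 genes lay on all arrays. For a gene under it on all arrays of a group, the fold is given as "at least". It is the brighter group's mean log2 deposited intensity, without background correction, against the mean of the higher of that median and the gene's own value. This scale was chosen after the data were seen, because bounds on the background-corrected scale lay above the folds of the deposited means. The bound is not a detection call.

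Before the data were examined, 26 gene lists were fixed, among them markers of other cell types. Each was tested with camera (preset correlation 0.01), adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Also fixed were the rule for named genes, the neighbour test and the test of response size. The rule named Fcer1g, the 10 highest and 10 lowest log2 fold changes among genes called, and in each list that passed camera or held a called gene up to 4 members with the largest absolute log2 fold change. Where fewer than 10 genes were called, it named all of them and the 5 with the smallest p in each direction, and it replaced provisional gene names by the next gene. The neighbour test was Fisher's exact test, two-sided, on genes called among the 150 annotated genes on each side of Fcer1g. Response size was the median signed difference of response over genes called for the mean response, with fry. On simulated data with 50 genes changed per fold size among 16593, the fit called 86 to 94% of genes with a 1.5-fold change in the 4 simple contrasts, 94 to 100% of those with 2-fold, and 4 to 13 unchanged genes. The simulated genes were independent, with spreads drawn from the fitted prior. Alternatives were a replicate block, median centring, no background correction, every probe, only the groups compared, a trended and robust prior, a fold of at least 2, and leaving out each sample in turn. An offset of 16, the brighter genes alone and 75 genes on each side of Fcer1g were added after the data were seen. Figures were drawn with matplotlib 3.10.9.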

Results

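The series measured messenger RNA in peritoneal macrophages, the resident phagocytes washed from the abdominal cavity of mice, on 8 Illumina MouseRef-8 bead arrays. Cells of C57BL/6 mice with the gene for the Fc receptor γ chain intact (WT) or knocked out (FcgKO) were kept without stimulation or with IFNγ, the cytokine that activates macrophages, for 6 h at 10 ng/ml. The chain, encoded by Fcer1g, is a membrane adaptor that carries an immunoreceptor tyrosine-based activation motif and pairs with activating Fc receptors and other receptors. Each of the 4 groups held 2 samples. The labels do not say whether these came from separate animals or wells, so the p-values measure only the spread between these samples, which may be technical. Array medians of the deposited intensity lay between 102.98 and 103.02, and the log2 values of the replicates correlated across probes with r between 0.9959 and 0.9969. Probes are not independent replicates, and the number of arrays limits the precision. The first principal component, with 68.0% of the variance, parted unstimulated from stimulated samples. The second, with 15.4%, parted WT, at 7.79 to 10.7, from FcgKO, at -14.7 to -5.97.

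Fcer1g was measured first, as a check of the labels. Its normalised intensity was 17959 ± 554 (mean ± SD, n = 2) in unstimulated WT samples and 17669 ± 964 in WT samples with IFNγ. In FcgKO samples it was 95.7 ± 0.0522 without and 103 ± 5.82 with IFNγ, which is about the array median. The deposited intensity of FcgKO samples was at least 174-fold lower without IFNγ (limma adjusted p = 5.2e-13). With IFNγ limma called it lower too (adjusted p = 6.6e-13), and no fold is given, because only 1 of the 2 FcgKO arrays was above its median. The labels of all 8 samples matched these levels. IFNγ had no called effect on Fcer1g in WT (log2 -0.02 (SE 0.08), adjusted p = 0.931).

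**Figure D1:**
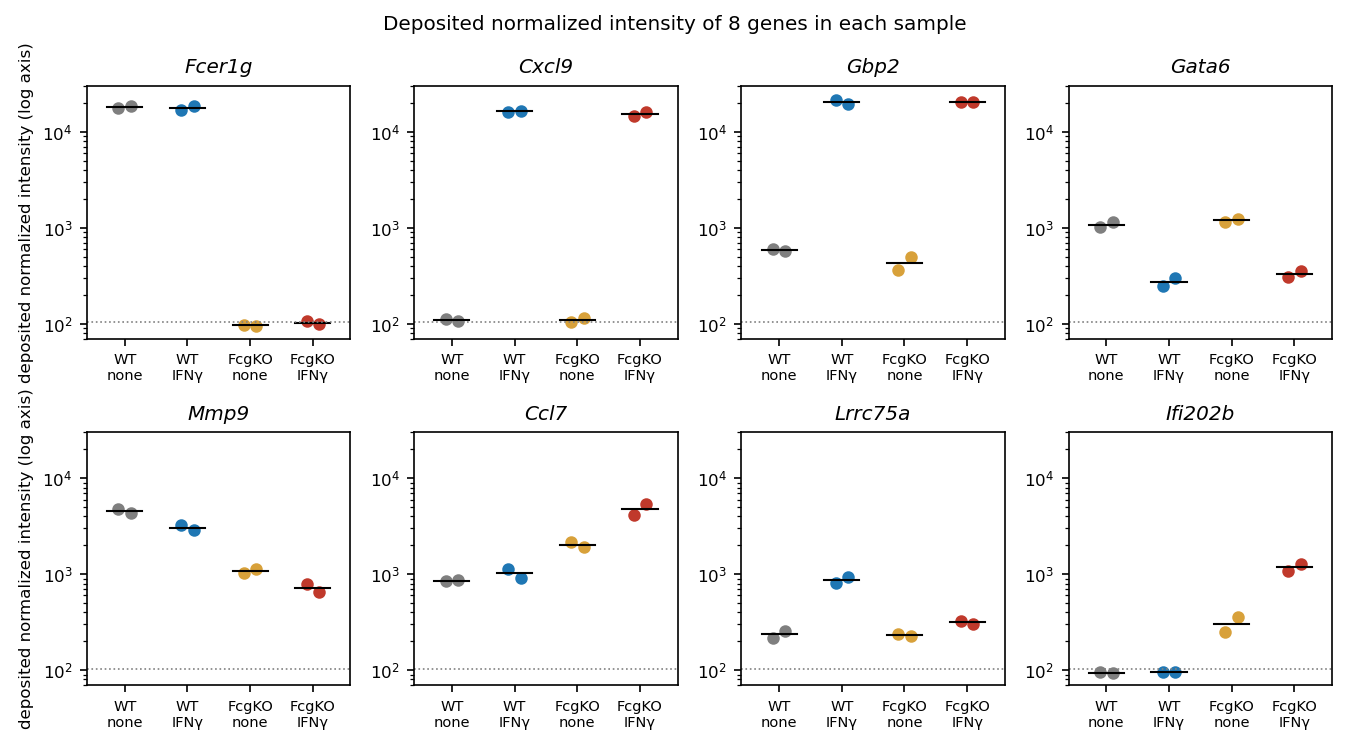
Deposited normalised intensity (log axis) of 8 genes in each of the 4 groups. Points are single samples, black bars the mean of 2 samples, and the dotted line the mean of the array medians. Fcer1g lay near the dotted line in the 4 FcgKO samples, Mmp9 was lower and Ccl7 higher in FcgKO, and Ifi202b lay near the dotted line in the 4 WT samples.

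The response of WT macrophages to IFNγ was asked first. The chemokines Cxcl9 and Cxcl10, which draw in T cells, rose most: Cxcl9 from 108 ± 4.06 to 16333 ± 195 in normalised intensity (log2 7.80 (SE 0.09) after and 7.238 without background correction, adjusted p = 2.2e-12) and Cxcl10 from 195 ± 35.9 to 12715 ± 1236 (log2 6.33 (SE 0.30)). Gbp2 (log2 5.22), Upp1, the uridine phosphorylase (4.89), the transcription factor gene Batf2 (4.85), Gbp3 (4.70), Igtp (4.63), Ifi47 (4.14), Gbp5 (at least 10.9-fold in deposited intensity) and Calhm6 (adjusted p = 8.3e-12) completed the 10 largest rises on the background-corrected scale. No fold is given for Calhm6, because only 1 of the 2 unstimulated arrays was above its median. The neutrophil chemokines Cxcl1 (log2 -3.04 (SE 0.32)) and Cxcl2 (-1.86 (SE 0.23)) fell, as did Idh1 (-2.76), Sel1l3 (-2.59), Thbs1, the gene of thrombospondin 1 (-2.40), Zdhhc14 (-2.29), Serpinb2 (-2.29), Ank (-2.12) and Nuak1 (adjusted p = 1.6e-07). Gata6, the transcription factor gene that marks large peritoneal macrophages, fell from 1078 ± 83.9 to 273 ± 36.7 (log2 -2.14 (SE 0.12), adjusted p = 5.2e-07).

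Of the 17 tested members of the list of IFNγ-inducible GTPases, which act against intracellular pathogens, 12 rose and none fell in WT (adjusted p = 0.00502 with an estimated correlation). In the list of MHC class I presentation, 15 of 17 rose, among them the transactivator gene Nlrc5 (log2 2.70), the peptide transporter gene Tap1 (2.58) and the immunoproteasome subunit gene Psmb9 (2.46), with an adjusted p = 0.00502 with an estimated correlation. IFN signalling genes rose in 12 and fell in 1 of 20, with Irf1 (3.61), Socs3 (2.89) and Socs1 (2.55) at the top (adjusted p = 0.0322 with an estimated correlation). Inflammatory genes rose in 12 of 21, including Icam1 (2.48), Il1rn (2.36) and Tnf (2.32), with an adjusted p = 0.0322 with an estimated correlation. These 4 lists also passed camera with the preset correlation of 0.01. Antiviral genes known from the type I IFN response rose in 21 of 25, led by Isg15 (2.75) and Oasl1 (2.53), but the call was lost with an estimated correlation (adjusted p = 0.0811). The same held for the chemokine list (7 of 18 rose and 2 fell, adjusted p = 0.12), MHC class II presentation (6 of 15 rose, led by Cd40 at 3.01 and Cd86 at 1.72, adjusted p = 0.207) and microbicidal effectors (7 of 16 rose and 1 fell, led by Casp4 at 2.40 and Nod1 at 2.35, adjusted p = 0.123). Adjusted over the list alone, the members that rose numbered 12, 16, 13, 12, 22, 8, 6 and 8, in the order given. In the class II list, Cd40 and Cd86 encode co-stimulatory receptors. Its members H2-DMa and Ciita rose less, by 1.21 and 0.80, and Ciita lost its call without some samples. Of 9 Fc receptor genes 3 rose, with Fcgr4 at 2.72 and Fcgr1 at 0.59, and the list did not pass camera (adjusted p = 0.14). The list of large peritoneal macrophage identity did not pass either (adjusted p = 0.4): of its 17 members 7 fell, including Gata6 and Serpinb2, and 3 rose, including Selp (2.55) and Timd4 (1.58).

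In all, limma called 2210 of 16593 genes at an adjusted p below 0.05 in WT, 920 higher and 1290 lower with IFNγ, and of these 235 rose and 76 fell by at least 2-fold. Without WT IFNγ replicate 2 it called 1399, 684 higher and 715 lower, and without replicate 1 of that group 700 higher and 807 lower. With a background offset of 16, chosen after the data were seen, 748 were higher and 810 lower. Of the 92 named genes called, 75 kept their call without each sample in turn. Fold changes of dim genes are understated, because the background correction adds an offset of 50.

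The same comparison in FcgKO macrophages asked whether the response needs the chain. Cxcl9 (log2 7.69 (SE 0.09) after and 7.133 without background correction) again rose most. The 10 largest rises on the background-corrected scale also held Cxcl10 (adjusted p = 2.7e-07, with no fold, as only 1 of the 2 unstimulated arrays was above its median), Gbp2 (log2 5.72), Upp1 (5.58), Calhm6 (at least 20.3-fold in deposited intensity), Igtp (4.79), Gbp3 (4.65), Batf2 (4.52), Ifi47 (4.31) and Irf1 (3.94). Cxcl1 (-2.52 (SE 0.32)), Thbs1 (-2.32), Cxcl2 (-2.26), Zdhhc14 (-2.11), Sel1l3 (-2.04), Serpinb2 (-1.99), Gata6 (-1.97), Idh1 (-1.97), Gpr183 (-1.94) and Nuak1 (-1.86) fell most. The GTPases rose in 12 of 17 (adjusted p = 0.00457 with an estimated correlation), MHC class I presentation in 16 of 17 (0.00457 likewise), IFN signalling in 13 of 20 with 1 fall (0.0227 likewise), inflammatory genes in 9 of 21 (0.0325 likewise) and antiviral genes in 22 of 25 (0.0474 likewise). Among the calls lost with an estimated correlation were those of the chemokines (8 of 18 rose and 3 fell, adjusted p = 0.073), MHC class II presentation (6 of 15 rose, 0.109), microbicidal effectors (4 of 16 rose and 1 fell, 0.109) and Fc receptors (0.268). In all, 12 lists passed camera in FcgKO, and 5 did with an estimated correlation. Of the 9 Fc receptor genes, Fcgr4 (1.99) and Fcgr1 (1.34) rose and Fcgr2b (-0.48), the inhibitory receptor gene, fell. Adjusted over the list alone, 12, 16, 13, 11, 22, 8, 6, 5 and 4 members rose, in the order given. Limma called 2028 genes, 841 higher and 1187 lower, and 225 rose and 59 fell by at least 2-fold. Without FcgKO unstimulated replicate 1 it called 1215, 594 higher and 621 lower, and without replicate 2 of that group 1350, 636 and 714. With the offset of 16 the split was 692 and 690. Of the 89 named genes called, 76 kept their call without each sample in turn.

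The calls of both genotypes overlapped. They shared 646 genes that rose, against 46.6 for independent lists, and 769 that fell, against 92.3. Only 2 genes, Tiam1 and Xdh, were called in opposite directions, both lower in WT and higher in FcgKO, and they are named because there were so few. Across all 16593 genes, which are not independent replicates, the log2 responses correlated with r = 0.884. The groups compared share no samples, but each gene's spread comes from the same fit, so the lists of calls are not independent. Of 2821 genes called in either genotype, 2693 moved the same way in both.

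**Figure D2:**
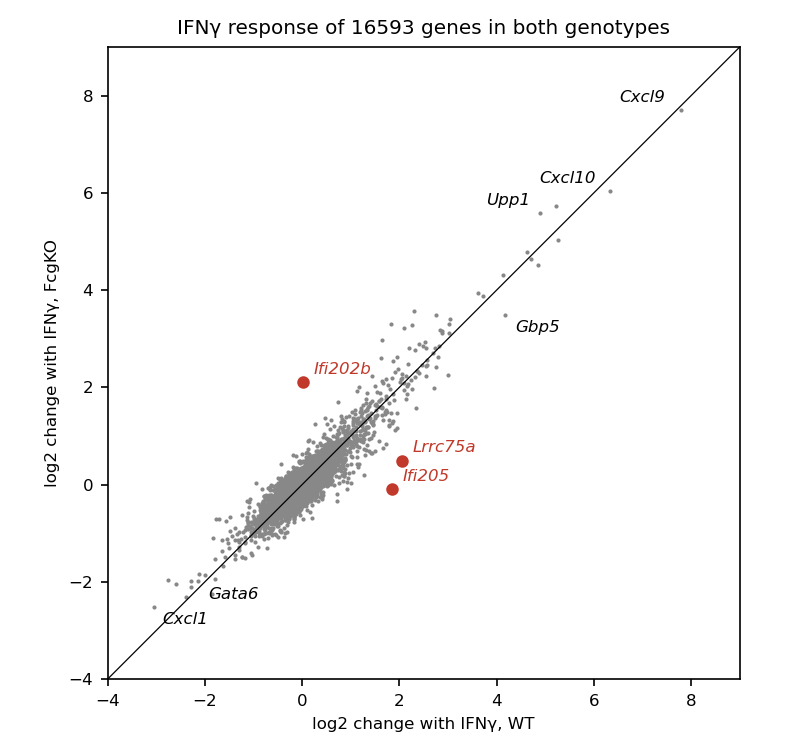
Log2 change with IFNγ in FcgKO (vertical axis) against that in WT (horizontal axis), 1 point per gene for 16593 genes. The line marks equal change, and red points are the 3 genes whose responses differed at an adjusted p below 0.05 (Ifi202b, Lrrc75a and Ifi205). Most points lie along the line, with r = 0.884.

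Unstimulated FcgKO and WT macrophages were compared to ask what the missing chain changes at rest. Besides Fcer1g, transcripts of the matrix metalloproteinase gene Mmp9 fell from 4577 ± 257 in WT to 1070.2 ± 73.4 in FcgKO (log2 -2.13 (SE 0.10), adjusted p = 6.3e-06), and those of haptoglobin, Hp, from 2103 ± 14 to 499.9 ± 117 (log2 -2.18 (SE 0.18), adjusted p = 0.00021). Uap1, which makes UDP-N-acetylglucosamine, was lower (log2 -2.44 (SE 0.15)), as were Vsig8 (-1.88), H2-M2 (-1.68), Cxcl1 (-1.66), the B cell chemokine gene Cxcl13 (-1.64), the glutathione transferase gene Gsta3 (-1.52) and the prostaglandin E synthase gene Ptges (-1.52). Higher in FcgKO were the monocyte chemokine genes Ccl7 (log2 1.28 (SE 0.13), adjusted p = 0.00115), Ccl12 (1.24) and Ccl2 (0.90), with Ccl6 (1.00), Plau (1.10), Daglb (0.89) and Prrc1 (0.84). Ifi202b, an IFN-inducible gene, was at least 2.91-fold higher in deposited intensity. Fcgr3, which encodes a receptor that pairs with the chain, rose from 4943 ± 6.95 to 11496 ± 136 (log2 1.22 (SE 0.07)), and Aim2, a sensor of cytosolic DNA, was higher by 0.99. Of these genes, Uap1, Vsig8, Fcgr3, Aim2 and Ifi202b lie within 150 genes of Fcer1g on its chromosome.

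Limma called 136 genes in this comparison, 48 higher and 88 lower in FcgKO, of which 7 and 19 by at least 2-fold. Count and split depended on single samples: 166 without WT unstimulated replicate 2 (84 higher and 82 lower), 75 without replicate 1 of that group (15 and 60), 36 without FcgKO unstimulated replicate 2 (11 and 25), 48 without replicate 1 of that group (14 and 34), and 83 without either WT IFNγ replicate (24 and 59). It was 80 with a background offset of 16, a setting chosen after the data were seen (22 and 58), and 90 without background correction (29 and 61). Of the 34 named genes called, 16 kept their call without each sample in turn, among them Mmp9, Hp, Uap1, Vsig8, H2-M2, Gsta3, Ccl7, Fcgr3, Aim2, Daglb and Ifi202b. Cxcl1, Cxcl13, Ptges, Plau, Prrc1, Ccl2, Ccl6 and Ccl12 did not, with a highest adjusted p between 0.072 and 0.330 in those fits.

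With IFNγ, the differences between the genotypes were compared again. Ccl7 reached 4806 ± 901 in FcgKO against 1029 ± 162 in WT (log2 2.26 (SE 0.13), adjusted p = 1.1e-05), and Ccl2 (1.80), Ccl12 (1.64), Rin2 (1.39), Ccl6 (1.23), Fcgr3 (1.22), Emp1 (1.15), Mtus1 (1.14) and the sulfotransferase gene Chst1 (1.12) were also higher. In deposited intensity, Ifi202b was at least 11.4-fold higher and Ifi205, of the same gene family, at least 3.5-fold lower. Mmp9 fell from 3056 ± 266 to 726 ± 93.8 (log2 -2.13 (SE 0.10), adjusted p = 3.2e-06). Uap1 (-2.55), Hp (-1.98), Vsig8 (-1.77), Ptges (-1.77), Gsta3 (-1.62), H2-M2 (-1.59) and Lrrc75a (-1.58) were lower as well. Limma called 476 genes, 207 higher and 269 lower in FcgKO, with 20 and 44 by at least 2-fold. It called 218 without WT IFNγ replicate 2 (91 higher and 127 lower), 225 without replicate 1 of that group (78 and 147), 267 without FcgKO IFNγ replicate 2 (102 and 165), 519 without replicate 1 of that group (261 and 258) and 288 with a background offset of 16 (109 and 179). Of the 53 named genes called, 33 kept their call without each sample in turn. Chst1 lost it without WT IFNγ replicate 1, either FcgKO unstimulated replicate or FcgKO IFNγ replicate 1 (highest adjusted p = 0.202).

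Unstimulated and stimulated cells shared called genes between the genotypes. Both comparisons called 28 genes higher, against 0.599 for independent lists (Fisher's exact test, two-sided, p = 1.0e-41), and 66 lower, against 1.43 (p = 3.1e-102), and 0 in opposite directions, with no sample in common. Genes are not independent replicates in this test. Each gene's spread also comes from the same fit in both comparisons, so the lists of calls are not independent. The p-values assume that they are, and may be too small. Across genes the log2 differences correlated with r = 0.582. Of the 518 genes called in either condition, 466 differed the same way in both.

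By gene list, 4 of 21 inflammatory cytokines and NF-κB targets were lower in FcgKO without and 8 with IFNγ, and 8 and 10 adjusted over the list alone. The list passed camera in both conditions, and its call was lost with an estimated correlation (adjusted p = 0.179 and 0.271). Tnf, the tumour necrosis factor gene, fell by 0.94 on the log2 scale without and by 1.05 with IFNγ, Icam1 (-0.98) and Nfkbia (-1.14) were lower at rest, and Tnfaip3 (-0.84) with IFNγ. At rest Tnf lost its call without WT unstimulated replicate 2 or either FcgKO unstimulated replicate (highest adjusted p = 0.162), and Nfkbia without WT unstimulated replicate 1, either WT IFNγ replicate or either FcgKO unstimulated replicate (0.212). Of the mast cell and basophil markers, 4 of 10 fell at rest and 6 with IFNγ (6 in both adjusted over the list alone), with list medians of -0.48 and -0.65. Their call was also lost with an estimated correlation (adjusted p = 0.204 and 0.36). The mast cell protease gene Cma1 fell from 591 ± 76.9 to 270.3 ± 45.1 (log2 -1.25 (SE 0.14)) and the carboxypeptidase gene Cpa3 from 477 ± 39.5 to 263 ± 19.7, a call lost without FcgKO unstimulated replicate 1 (adjusted p = 0.076). Chemokines went both ways, with 4 of 18 higher and 2 lower at rest and 5 higher and 3 lower with IFNγ, and the list did not pass camera (adjusted p = 0.64 and 0.77). Among Fc receptors, 2 of 9 were higher and 2 lower at rest, and 4 and 2 with IFNγ, when Fcgr1 was higher by 1.10 and Fcer1a lower (log2 -0.77). Besides Fcer1g, the members called at rest were Fcgr2b, Fcgr3 and Fcer1a, which all lie within 150 genes of Fcer1g. That list's mean (-0.64 at rest) and median (0.22) differed in sign because Fcer1g is a member, and it did not pass camera. Immediate early genes fell in 2 of 16 at rest and 3 with IFNγ, with Egr2 at -0.56 and -0.97 (at rest lost without either FcgKO unstimulated replicate, list adjusted p = 0.204 and 0.36 with an estimated correlation). Of 23 ITAM adaptor and partner receptor genes, Clec4e, a receptor gene whose product pairs with the chain, was lower at rest (log2 -0.71), a call lost without either FcgKO unstimulated replicate (highest adjusted p = 0.066), and with IFNγ (-1.37), and the list did not pass camera (adjusted p = 0.15 and 0.99). In all, 13 lists passed camera at rest and 8 with IFNγ, and 0 with an estimated correlation. Without WT unstimulated replicate 1 these were 5 at rest, without FcgKO unstimulated replicate 2 they were 8 at rest, and without WT IFNγ replicate 1 they were 5 with IFNγ.

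**Figure D3:**
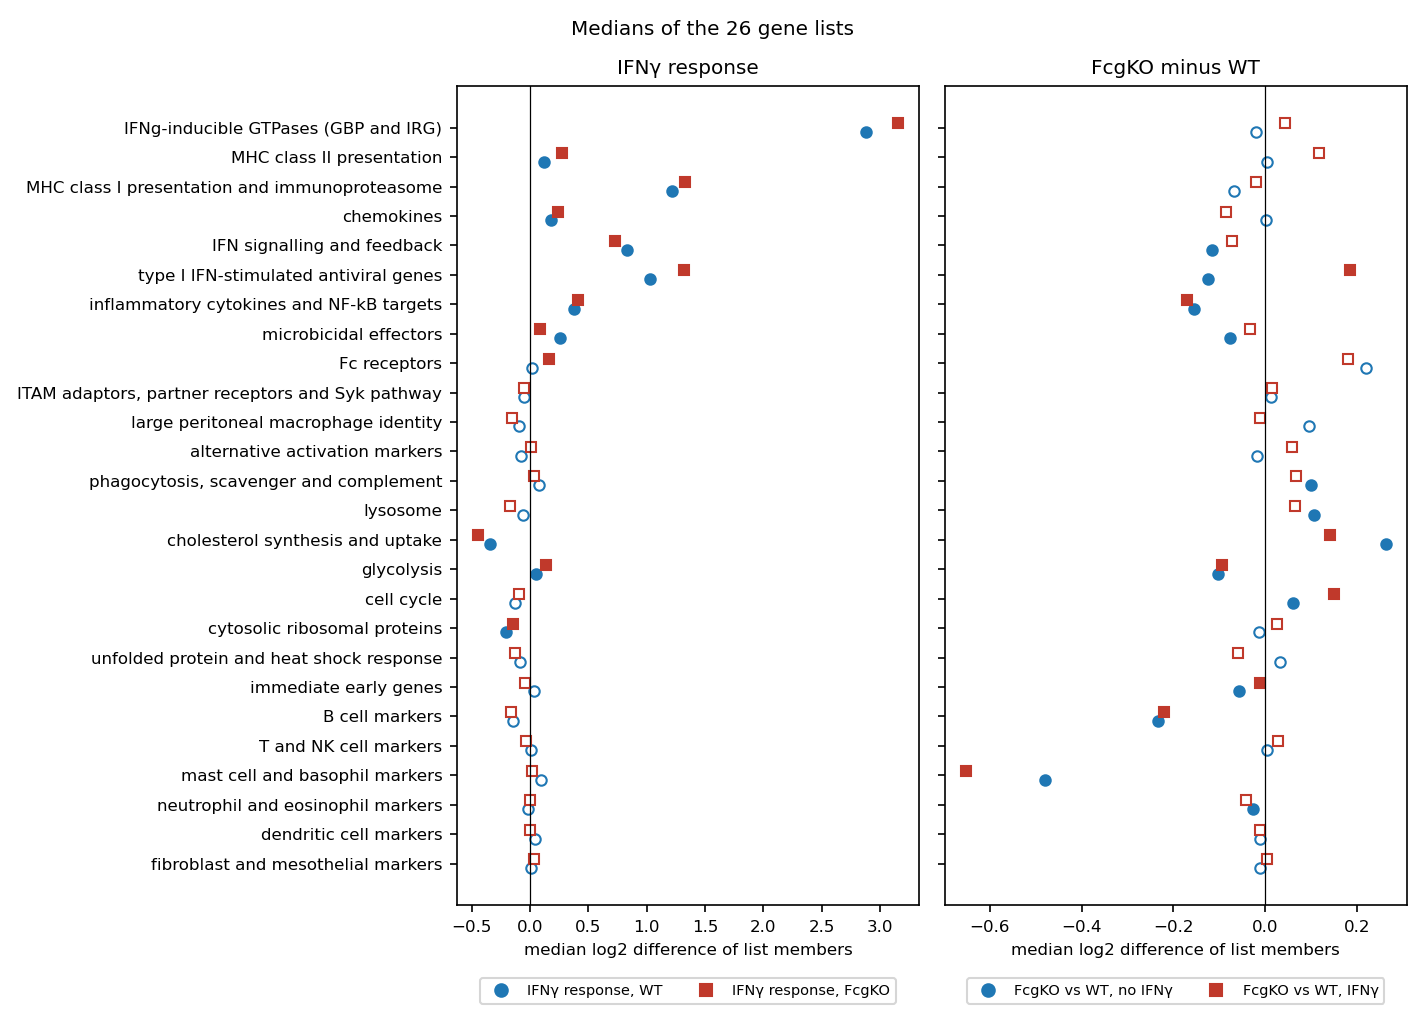
Median log2 difference of the members of each of 26 gene lists, for the IFNγ response in both genotypes (left) and for FcgKO minus WT in both conditions (right). Filled symbols passed camera at an adjusted p below 0.05 with a preset correlation of 0.01. The GTPase list had the highest medians with IFNγ, 2.88 in WT and 3.16 in FcgKO, and mast cell and basophil markers the lowest for FcgKO minus WT, -0.48 and -0.65.

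Whether the response to IFNγ itself differed between the genotypes was tested as an interaction. Ifi202b rose with IFNγ in FcgKO from 305 ± 78 to 1182 ± 149.6 and was at 94.3 ± 1.67 and 94.9 ± 0.465 in WT (adjusted p of the difference of responses = 0.00962). Ifi205 rose in WT from 125 ± 7.21 to 364 ± 71.3 and was at 95.8 ± 0.469 and 92.2 ± 2.55 in FcgKO (adjusted p = 0.00437). No size is given for these 2 genes, because Ifi202b in WT and Ifi205 in FcgKO lay under the array median. Lrrc75a rose in WT from 238 ± 27.4 to 872 ± 76.6 and was at 233 ± 8.02 and 314 ± 19 in FcgKO (difference of log2 responses -1.56 (SE 0.15), adjusted p = 0.00437). A second probe of Lrrc75a gave -1.41 and 2 other probes 0.01 and -0.07, and among other probes 1 of 2 of Ifi202b and the only one of Ifi205 had the same sign. Ifi202b and Ifi205 lie near Fcer1g and belong to a family of similar genes whose transcripts a probe may not tell apart.

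These 3 genes were the only ones called, against 1193 at an unadjusted p below 0.05. The count was 0 without background correction, 11 with every probe tested, 22 with a trended and robust prior, and 37 without FcgKO IFNγ replicate 1. It was 9 and 1 without WT unstimulated and WT IFNγ replicate 2, and 1 and 5 without FcgKO unstimulated replicate 1 and 2. Each gene lost its call without some sample: Ifi202b without either WT IFNγ replicate (highest adjusted p = 0.122), Ifi205 without FcgKO unstimulated replicate 1 (0.053) and Lrrc75a without that sample or WT IFNγ replicate 2 (highest 0.068). Next by p, without passing, were Fcgr1 (difference 0.74, adjusted p = 0.0597), Tlr13 (1.07, 0.0637), Olfml2b, Rnase2a and Mtus1 with larger responses in FcgKO, and Cdkn1a (-0.88, 0.0597), Tarm1, Mocs1, Enc1 and Cd1d1 with smaller ones. In simulated data the test of this difference called 66% of genes with a 1.5-fold difference and 100% of those with 2-fold. Those simulated genes were independent, with spreads drawn from the fitted prior, so the shares do not carry over to these data. Tlr13, with a difference of over 2-fold (log2 1.07), was not called. Over the 3182 genes called for the mean response (1194 higher and 1988 lower), the response was smaller in FcgKO for 1670 (52.5%), and the median difference, signed by direction, was -0.012 on the log2 scale (quartiles -0.15 and 0.11), which did not pass limma's fry at 0.05. It turned to 0.0065 without FcgKO unstimulated replicate 2, to 0.015 without FcgKO IFNγ replicate 1 and to 0.011 over genes changed at least 2-fold, and reached -0.046, past fry's threshold, without WT unstimulated replicate 1.

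Among the gene lists, only that of antiviral genes passed camera for the difference, with a mean of 0.43 and a median of 0.33 (25 genes, camera adjusted p = 5.8e-11). None of its members was called over all genes, and 7 were higher adjusted over the list alone. Its largest differences, none called, were Ifit3 (1.49 (SE 0.42), adjusted p = 0.45), Rsad2 (1.34 (SE 0.49), 0.581) and Ifit2 (1.03 (SE 0.19), 0.126). With an estimated correlation the adjusted p = 0.872, and with fry 0.935. The number of lists that passed was 2 without replicate 1 of unstimulated WT or of WT with IFNγ, 3 without WT unstimulated replicate 2 or FcgKO unstimulated replicate 1, and 4 without FcgKO IFNγ replicate 2.

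Fcer1g lies on chromosome 1, and whether genes near a targeted gene were called more often than others was tested next. Among the 150 annotated genes on each side, 14 of 113 tested (12.4%) were called between the genotypes at rest, against 121 of 16469 elsewhere (0.735%), an odds ratio of 19.1 (95% interval 9.79 to 34.7, Fisher's exact test, two-sided, p = 3.9e-13). With IFNγ these were 16 of 113 (14.2%) and 459 of 16469 (2.79%), an odds ratio of 5.75 (3.14 to 9.92, the same exact test, p = 1.4e-07). Of the near genes called, 4 were higher and 10 lower in FcgKO at rest, and 5 and 11 with IFNγ. They included the SLAM family receptor genes Cd48 (under the array median in FcgKO) and Ly9 (log2 -0.86 at rest and -0.63 with IFNγ), chosen after their values were seen, and Fcgr2b (0.73 and 0.52). Of the 2 other probes of Fcgr2b, 1 was called at rest (0.65, adjusted p = 0.00153) and the other was not (0.08, adjusted p = 0.918), and neither was called with IFNγ (0.03 and -0.06, adjusted p = 0.947 and 0.881). At rest the odds ratio was 46.3 and 37.4 without FcgKO unstimulated replicate 2 and 1, 34.9 without WT unstimulated replicate 1, 30.9 without either WT IFNγ replicate and 35.6 with a background offset of 16. With IFNγ it was 9.42 without WT IFNγ replicate 2. Other left-out samples lowered the odds ratio. At rest it was 13.97 without either FcgKO IFNγ replicate and 15.27 without WT unstimulated replicate 2. The lowest with IFNγ was 4.109, without FcgKO IFNγ replicate 1. With a fold of at least 2 it was 48.4 at rest and 22.7 with IFNγ, and with 75 genes on each side 31.6 and 8.275.

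**Figure D4:**
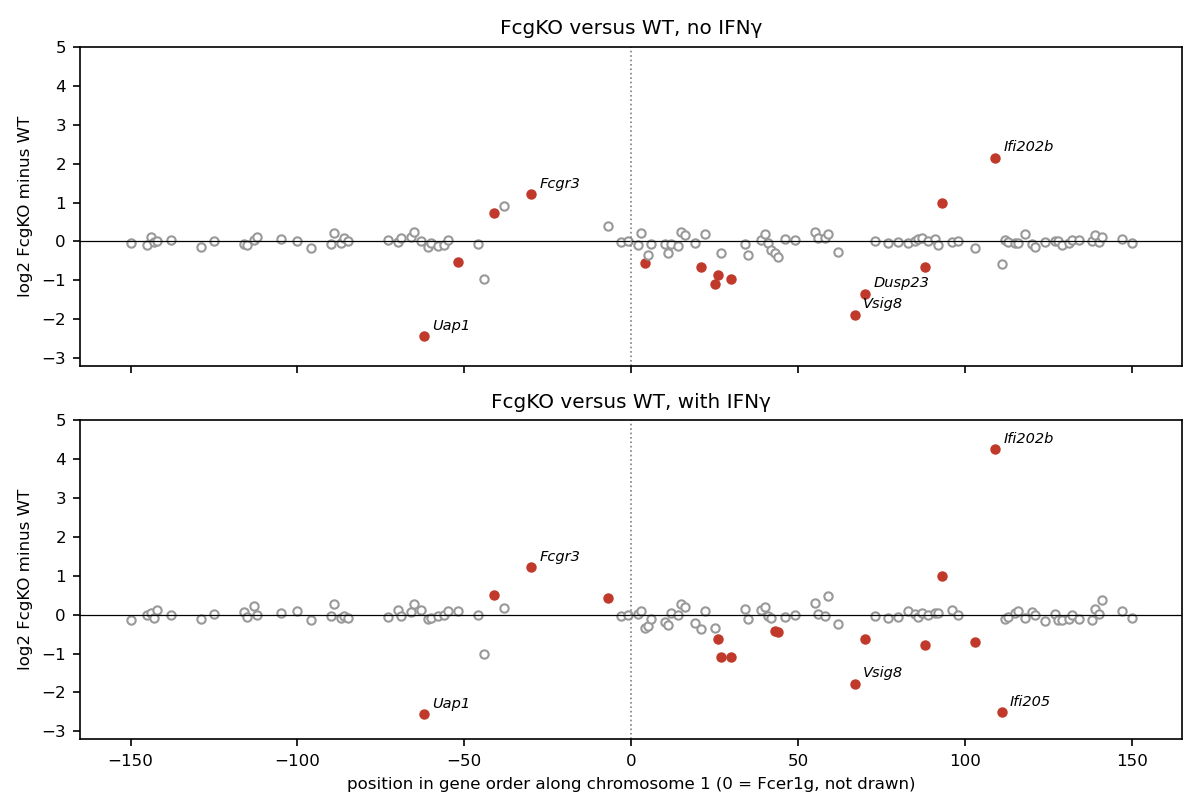
Log2 difference FcgKO minus WT (vertical axis) of the tested genes among the 150 on each side of Fcer1g, by gene order along chromosome 1 (horizontal axis), without (top) and with IFNγ (bottom). Filled points were called at an adjusted p below 0.05, 14 at the top and 16 at the bottom, and the furthest from 0 are named.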

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

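The tests that weigh explanations in this part were chosen after the results were seen, and those on single probes and on mast cells as the whole source were reworded after their own values were seen, while the neighbour test and leaving out each sample were planned. Ifi202b, Ifi205, Lrrc75a and the list of antiviral genes stand here because their response to IFNγ differed between the genotypes by a test of that difference. The other results of this part did not enter by that rule.

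Ifi202b responded more in FcgKO, by 2.097 on the background-corrected log2 scale, and Ifi205 less, by -1.945. These values are not measured sizes, because Ifi202b in WT and Ifi205 in FcgKO lay under the array median. Lrrc75a responded less too, by -1.556. The list of antiviral genes responded more in FcgKO, by a mean of 0.4262, but none of its 25 members was called and the call of the list was lost with an estimated correlation (adjusted p = 0.872) and with fry (0.935).

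Genes called between the genotypes gathered near Fcer1g, among them Ifi202b and Ifi205. A loss of the chain that acts alike on genes anywhere would leave the odds ratio near 1, and its lower 95% bound was 3.14 in the condition where it was lower. Genes elsewhere were not matched for class, so an effect of the chain on Fc and SLAM family receptor genes, which gather there, could also raise the odds ratio. Probes that bind another strain's sequence less well would give lower signals in FcgKO, whereas at least 4 near genes were called higher in FcgKO in each condition. This count does not test probes that bind such a sequence, or that of a similar gene, better. Fcgr2b is among the higher genes, although its 2 other probes were not called with IFNγ. Sdhc, called higher with IFNγ, had another probe at 0.07 (limma adjusted p = 0.821). A second probe of Ifi202b was called higher in both conditions and another in neither. For the lower genes, weaker probe binding cannot be told apart from a lower transcript level, because only 5 other probes exist. All 6 of their tests were lower in sign, but 33.3% were called lower. Chromosome of another strain flanking the targeted gene cannot be told apart from an effect of the chain on these neighbours. The odds ratio, 19.1 at rest and 5.75 with IFNγ, is the pattern itself, and genotypes of the flank were not measured.

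Mmp9, Hp, Fpr2 and Cma1 were lower in FcgKO, with Fpr2 at -1.19 (SE 0.10) at rest (chosen after its value was seen). Fewer mast cells in the FcgKO wells may account for Cma1, as the median of 10 mast cell and basophil markers was -0.479 at rest (-0.457 without Cma1 itself). The probes of Cma1 and Cpa3 were at 591 ± 76.9 and 477 ± 39.5 in WT, and intensities of different probes do not rank transcripts by abundance. Whether mast cells were the whole source of the lower Mmp9 and Hp cannot be told apart from a change in macrophages: both fell by more than the marker that fell most, by over 2 standard errors in both conditions at both background offsets. Once the array median was subtracted, this held for Mmp9 with IFNγ (-0.53) but not for Mmp9 at rest (-0.65) or for Hp, where the excess was as little as -0.44. Fewer neutrophils cannot be told apart either, since the median of their 14 markers was -0.027 with most near the array median. Mmp9, whose fall is to be explained, is 1 of the 14 and the only one called, so values of this list partly restate that fall, and without it the median was -0.0044 and the mean -0.083. With it the mean was -0.23, 4 were lower adjusted over the list alone, and the list passed camera at rest (adjusted p = 0.0039), a call lost with an estimated correlation (0.204). At rest S100a8 was at 2968 ± 626 in WT and 2121 ± 78.5 in FcgKO (log2 -0.48 (SE 0.13), adjusted p = 0.18) and S100a9 at 101 ± 2.36 and 98.8 ± 8.79. Cells that did not adhere were discarded, but how far this removed either cell type was not measured. An effect of the genotype on macrophages stays open as untested.

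The larger rise of antiviral genes in FcgKO did not rest wholly on a single array, as the mean difference stayed at 0.258 or more without each array. The camera call at the preset correlation also held. Part of the rise may rest on 1 array: for FcgKO minus WT at rest, the list mean was 0.00119 without FcgKO unstimulated replicate 1 and -0.3359 without replicate 2. Spread between samples shared by these genes may account for the larger rise, since the camera adjusted p with an estimated correlation was 0.872. A biological difference between the genotypes stays open, with 2 samples per group.

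Other splits of the samples were tested for the IFNγ response over both genotypes: of the 35 splits of the 8 samples into 4 and 4, only 1, the real one, called as many as its 2577 genes, and the highest other, the split by genotype, called 46. No split can give a share below 1 of 35, so this count alone cannot exclude chance. It shows only that no other split called as many genes as the real one. The other splits keep the IFNγ effect in their spread, which lowers their counts. The count says nothing of the size of the effect, and the samples may be technical replicates.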

How the results depend on the processing

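Alternatives with an offset of 16, the brighter genes or 75 genes on each side of Fcer1g were chosen after seeing the data; the others were planned. Normexp without control information and no filter became the main setting, log2 of the deposited values coincides with no background correction, and a stricter filter on detection p was not run, as its columns have no samples. Values of named genes were compared over the alternatives except left-out samples, every probe, a fold of at least 2 and 75 genes on each side. Of these values, 2638 kept their side of the threshold, 97 lost and 91 gained a call, and 0 reversed. Reversed here means a changed sign of a value called in either setting. A value called in neither counted as kept even where its sign changed. Over left-out samples these were 2932, 231, 93 and 0. Gene lists were compared over the same alternatives without only the groups compared, and also with an estimated correlation and with fry. For them the numbers were 965, 61, 14 and 0, and with samples left out 978, 32, 28 and 2. Median centring changed no call of a named gene. Dim signal limits folds, and the lone sample of a reduced group is assumed to vary like the other groups.

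The replicate numbers were not taken to pair the samples: deviations of same-numbered samples correlated at -0.006 to 0.236 over 6 pairs of groups, and 3 of these were over 0.1. With the replicate block the calls became 237 for FcgKO against WT at rest and 25 for the difference of responses. Without background correction these were 90 and 0. With offset 16, 80 genes were called at rest and 288 with IFNγ, and the share of higher genes became 48.0% in place of 41.6% for the WT response and 50.1% in place of 41.5% for FcgKO. With every probe 11 and with the trended and robust prior 22 genes differed in response. With a fold of at least 2, counts were 311, 284, 26 and 64 (fewer genes by construction), and the median difference of response turned to 0.01128. Lists that passed fell from 11, 12, 13, 8 and 1 to 4, 5, 0, 0 and 0 with an estimated correlation, and to 5, 5 and 0 for the last 3 comparisons with fry. The cause of these shifts was not tested otherwise.

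Leaving out 1 sample, calls ranged from 1399 to 2261 (IFNγ in WT), 1215 to 2203 (in FcgKO), 36 to 180 (FcgKO against WT at rest), 218 to 542 (with IFNγ) and 1 to 37 (difference of responses). Odds ratios near Fcer1g ranged from 13.97 to 46.28 at rest and 4.109 to 9.42 with IFNγ (48.39 and 22.71 with a fold of at least 2, and 31.59 and 8.275 with 75 genes on each side), and the median difference of response from -0.04582 to 0.01465, with 0.006467 without FcgKO unstimulated replicate 2. Lists that passed ranged from 11 to 13, 12 to 14, 5 to 12, 5 to 8 and 1 to 4. For FcgKO against WT at rest, 2 list means reversed, counting only lists called in either fit. These were cell cycle (-0.02712, without WT unstimulated replicate 1, to 0.1866) and antiviral genes (-0.3359 to 0.00119, without FcgKO unstimulated replicate 1).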

Other observations

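The gene lists described here were fixed before the data were examined. Cholesterol genes fell in 7 of 16 in WT and 9 in FcgKO, with Sqle, which encodes squalene epoxidase, at -1.38 (SE 0.19) and -1.54 (SE 0.19) and 1 riser, Ch25h, the cholesterol 25-hydroxylase gene, at 1.49 and 1.36 (adjusted p = 0.435 and 0.274 with an estimated correlation). Glycolysis genes rose in 5 and 4 of 16 and fell in 1 in each, with the hexokinase gene Hk3 at 2.79 (SE 0.07) and 2.62 (SE 0.07) (adjusted p = 0.321 and 0.268 likewise). Ribosomal protein genes fell in 5 and 2 of 17 (adjusted p = 0.321 and 0.331 likewise). Complement and scavenger genes, which did not pass camera, rose in 6 and fell in 3 of 21 in WT, with C2 at 2.14, Cfb at 1.67 and Cd93 at -1.50, and rose in 4 and fell in 3 in FcgKO. Lysosome genes fell in 4 and 5 of 18, with Ctsl, the cathepsin L gene, at -1.04 and -1.05, and 1 rose in each, Ctsc. Alternative activation markers fell in 3 of 14 and rose in 1, Mrc1 (1.13 and 0.95), in each genotype. Unfolded protein genes fell in 2 and 5 of 19 and rose in 1, Atf3, in each. Cell cycle genes fell in 3 and 1 of 20 and rose in 1, Ccnd1, in each, a call lost in some fits with a sample left out (highest adjusted p = 0.319 and 0.103). Immediate early genes rose in 4 and 3 of 16 and fell in 2 and 1. The lysosome, alternative activation, unfolded protein, cell cycle and immediate early lists did not pass camera in either genotype.

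Between the genotypes, 0 of 16 cholesterol genes were called over all genes by limma at rest and 1, higher in FcgKO, with IFNγ, and 6 and 1 were higher adjusted over the list alone. The list had a mean of 0.31 and 0.14 and passed camera, a call lost with an estimated correlation (adjusted p = 0.231 and 0.603). Markers of B cells, 12 genes, had a list mean of -0.27 in both conditions with 0 called, and passed camera in both but not otherwise (adjusted p = 0.537 and 0.603 with an estimated correlation). Neutrophil and eosinophil markers had 1 called gene of 14, Mmp9, in both, and 4 at rest and 2 with IFNγ were lower adjusted over the list alone. That list passed camera at rest (adjusted p = 0.0039) and fry in both conditions (adjusted p = 0.028 and 0.021), but not camera with an estimated correlation (adjusted p = 0.204 and 0.509). T and NK cell, dendritic cell, and fibroblast and mesothelial markers had 0 genes called between the genotypes by limma, of 17, 12 and 16 tested, and did not pass camera. With IFNγ, Blnk of the B cell list fell by 1.03 in WT and Hdc of the mast cell list rose by 1.29, and none of the 6 lists of other cell types passed camera in either genotype.

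Other lists passed camera between the genotypes and lost the call with an estimated correlation. Antiviral genes had a mean of -0.17 at rest and 0.26 with IFNγ, where Ifit2 (0.81) and Oas3 (0.42) were called (adjusted p = 0.436 and 0.562 with an estimated correlation). The mean at rest turned to 0.00119 without FcgKO unstimulated replicate 1, and Ifit2 lost its call without either WT IFNγ replicate or FcgKO IFNγ replicate 2 (highest adjusted p = 0.108). Glycolysis genes had a mean of -0.11 and -0.14 (adjusted p = 0.368 and 0.509 likewise) and cell cycle genes 0.08 and 0.15, with Mcm6 (0.65) and Ccnd1 (0.71) called with IFNγ (adjusted p = 0.669 and 0.603 likewise). The mean of cell cycle genes at rest turned to -0.027 without WT unstimulated replicate 1, and Ccnd1 lost its call without either WT IFNγ replicate or FcgKO IFNγ replicate 1 (highest adjusted p = 0.125). At rest only, IFN signalling (-0.13, adjusted p = 0.204 likewise), microbicidal effectors (-0.038, 0.391), complement and scavenger genes (0.14, 0.436) and lysosome genes (0.12, 0.359) passed camera.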
